A study of Mus musculus with 7 samples.

How the data were processed

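The study profiled CD4 T cells sorted as CD45+CD3+CD4+ from orthotopic lung tumours of C57BL/6 mice over 8 weeks old. Mice carried a loxP-flanked I-Ab allele, which encodes an MHC class II chain, and were given tamoxifen. The Control group (I-AbF/F, 5 libraries) had no Cre, and the Cre group (I-AbF/F Col1a2-cre, 2 libraries) carried Cre under the fibroblast-expressed Col1a2 promoter, so the deletion was aimed at fibroblasts and not at the sorted cells. Total RNA was extracted with a NucleoSpin kit and made into 3′ UTR RNA-seq libraries with an NEB Next Ultra kit, per the labels' protocols. The series design names the libraries biological replicates matched for gender and age, while counts of Xist and of Y-linked genes differed between libraries within and between the groups. Each library was placed in its group from its title.

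The first deposited file holds raw counts per 3′ region, per the file headers, as whole numbers for 116000 regions of 55364 genes in 7 libraries. The submitters' processing notes name FastQC 0.11.8, HISAT2 2.1.0, DESeq2 and the build mm10. The tool that counted the regions, its use of strand and the annotation release are not given in the sources used here. The second deposited file is the authors' comparison of Cre with Control. Its p-values and FDR come from DESeq2, per the file headers. The deposited fold is a ratio of normalized values, and the authors give the same contrast as a log2 fold change. The GC content of each gene stands in the deposited table as a percent. GENCODE M21, which is on the same build, held 55104 of the genes, and 99.4% of these had the same chromosome, start, end and strand there, so that annotation was used to place the counted regions of Trim56, Col1a2 and H2-Ab1 against exons and UTRs. All coordinates count from 1.

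Counts were summed over the regions of each gene. Totals ran from 1484655 to 1724346 counts in Control and were 1929899 and 1449739 in Cre. A count of 0 allows up to 3 counts, which is between 1.55 and 2.07 CPM (counts scaled to the library's total) in a single library and 0.888 CPM over both Cre libraries. Such limits cover counting error only, since reads without molecular identifiers are not independent molecules. Regions that overlap a region of another gene on the same strand numbered 2449 and held 11.6% of counts, so genes such as Rpl13a and the snoRNAs within it cannot be separated with confidence. The same holds for members of gene families with near-identical copies. Mitochondrially encoded genes were not analysed here. No library pair agreed within sampling noise in a chi-square test over genes.

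The main test was the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, robust dispersion estimates, group as the only term and filterByExpr defaults (minimum count 10, minimum total 15), which kept 9854 genes. P-values were two-sided and adjusted by Benjamini-Hochberg with a threshold of 0.05. Log2 fold changes are Cre minus Control, and their standard error was taken from the F statistic. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, on logCPM values with a prior count of 2. There were 40 lists with 869 genes, covering T cell states, metabolism, survival, cytokine responses, other cell types and RNA handling, and 853 genes were found in the file, 5 of them under another symbol. The 31 lists with at least 5 tested genes entered the test. Sums of CPM over a list or a gene class take in all its members in the file, tested or not. Single values were compared by an exact two-sided permutation test, which cannot go below 0.0952 for 2 libraries against 5. The design, the lists, the alternatives and the rule for named genes were set before the data were examined.

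The rule named genes in several parts. Part 1 took up to 12 protein-coding genes per direction by fold change among those past the threshold with both Cre libraries outside the Control range, and, where fewer than 10 passed, filled to 10 by smallest p; T cell receptor and immunoglobulin segments, Gm-number and Rik symbols were left out. Part 2 took up to 4 members per list by smallest p, and those printed were chosen among them after their values were seen. Part 3 fixed a set of genes, including H2-Ab1, C1qbp, Cd4, Foxp3, Ifng, Tcf7 and Col1a2. Genes named outside the rule are said to be so.

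The alternatives were DESeq2 size factors, upper-quartile factors, no filter, a stricter filter (10 counts in 5 libraries), each library left out, the replicate number as a block, DESeq2 1.42.0, limma voom with and without library weights, and for lists an estimated correlation and fry. In 5 data sets simulated for Cre against Control over 9854 genes, with 200 changed genes in each, edgeR recovered 1% of genes lowered by a log2 of 2, 11.8% at 4, 18.9% at 6 and 34.6% at 8, and 12.9%, 47.9%, 52.9% and 60.2% of genes raised by those sizes. Of its calls, 4.81% were on unchanged genes. DESeq2 recovered between 12% and 81.4% of changed genes, with 52.5% of its calls on unchanged genes, on average 91.8 lower and 8.2 higher per data set. Camera called a list of 60 genes moved by a log2 of 2 in 5 of 5 data sets and 1 of 150 unmoved lists. These rates do not cover smaller shifts or lists of correlated genes. The simulated counts were drawn with edgeR's own dispersions and normalized library sizes, so the comparison with DESeq2 may favour edgeR. Each unchanged gene had 1 mean level over all libraries, so the many zeros of the Cre libraries were not built in. In the real data the ribosomal protein list had a median log2 fold change of 0.07 and an estimated correlation of 0.149.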

Results

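The question was whether CD4 T cells inside lung tumours express different genes when fibroblasts lack MHC class II. Transcripts were counted at their 3′ ends in sorted intratumoral CD4 T cells from 5 Control libraries and 2 Cre libraries. Total counts were 1685845, 1484655, 1626083, 1724346 and 1627755 in Control replicates 1 to 5 and 1929899 and 1449739 in Cre replicates 1 and 2. Fewer genes were detected in the Cre libraries at an equal total of 1449739 counts. Control libraries would hold 9983 to 14603 genes there, and the Cre libraries 8759 and 7896 (exact permutation p = 0.0952, two-sided, the smallest this design allows). The Y-linked gene Ddx3y, singled out after its values were seen, had 1, 34, 141, 2 and 0 counts in Control and 76 and 89 in Cre, and Xist, expressed from the inactive X chromosome, had 340, 16, 76, 266 and 476 counts in Control and 1 and 86 in Cre.

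**Figure D1:**
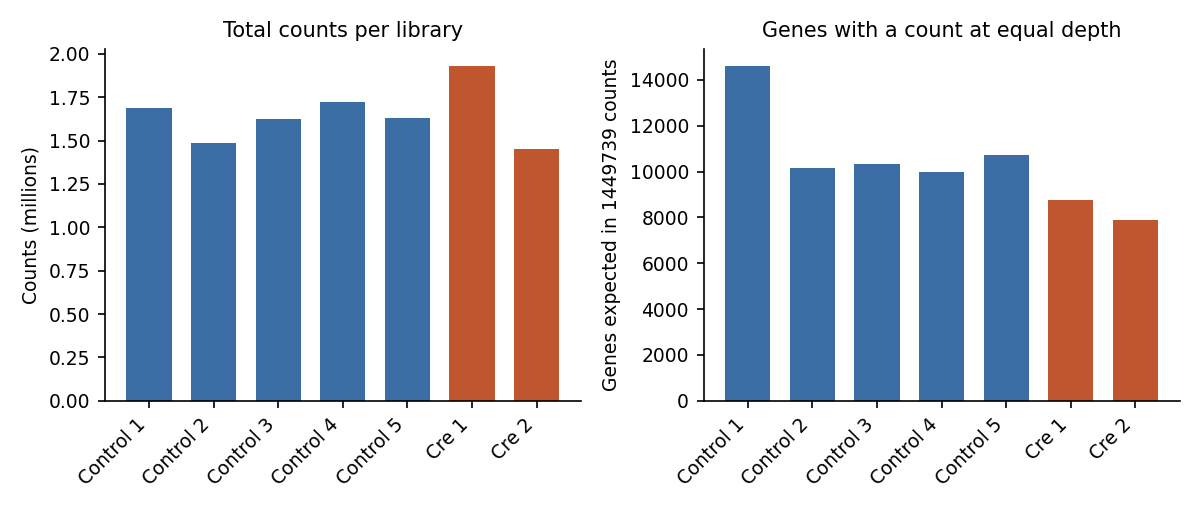
Total counts (left) and the number of genes expected in 1449739 counts (right) for each of the 5 Control libraries (blue) and 2 Cre libraries (orange). The totals overlap between groups, while the Cre libraries hold 8759 and 7896 genes at equal depth and every Control library at least 9983.

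Trim56, a ubiquitin ligase with a role in antiviral signalling, fell from 332 ± 83.1 CPM in Control (SD, n = 5) to 3.11 ± 1.47 CPM in Cre (n = 2), a log2 fold change of −6.67 ± 0.68 (SE; edgeR adjusted p = 0.0039). Its counts were 649, 382, 565, 412 and 706 in Control and 8 and 3 in Cre. No gene passed the threshold as higher in Cre, and 1 of 9854 tested genes passed as lower. At an unadjusted p under 0.05, edgeR gave 139 genes higher and 1001 lower. DESeq2 on the same genes called 35 higher and 607 lower, limma voom 3 higher and 0 lower, and voom with library weights 1 higher and 0 lower. The DESeq2 count, in a repeat added after seeing the data, moved to 32 higher and 380 lower without Control replicate 1 and to 93 higher and 1510 lower without Cre replicate 1. The edgeR count moved to 17 higher and 202 lower without Cre replicate 1 and to 15 higher and 28 lower without a filter on low counts, and neither form of voom called Trim56 (adjusted p = 0.222 and 0.789).

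Trim56 (ENSMUSG00000043279) lies on the minus strand of chromosome 5 at 137105644 to 137116209 (mm10). All of its counts came from 1 region, at 137105395 to 137112455. Of the 7061 bases of that region, 6812 lie in the annotated 3′ UTR and 249 lie past the gene's end. No counted region of another gene overlapped it on the same strand.

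The other 9 genes in the group of lowest p among those lower in Cre did not pass edgeR (adjusted p = 0.169 to 0.214) and did pass DESeq2. Riox2, a ribosomal oxygenase, stood at 89.4 ± 22.5 CPM in Control and had 0 counts in both Cre libraries, which is at least 100.8-fold lower against the limit over both. Crem, a transcription factor of cyclic AMP signalling, stood at 112 ± 65.7 CPM in Control and also had 0 counts in Cre (at least 126-fold lower). The splicing kinase Prpf4b (74.5 ± 29.0 CPM in Control), the death receptor Fas (75.2 ± 34.6 CPM) and the Polycomb-associated Mtf2 (84.4 ± 69.4 CPM) were likewise at 0 in both Cre libraries. Cyb5b, a cytochrome b5 of the mitochondrial outer membrane, had 176 ± 56.7 CPM in Control and 1.55 ± 2.20 CPM in Cre. Trnau1ap, Abhd2 and Snx2 had Control means of 130, 82.8 and 112 CPM and Cre means of 0.604, 0.259 and 0.518 CPM. In the same Cre libraries 25.01% and 33.6% of tested genes had no count, against 1.14% to 16.1% in Control. Of 6287 tested genes detected in all 5 Control libraries, 338 (5.38%) were at 0 in both Cre libraries, and of 5426 detected in both Cre libraries 1 was at 0 in all Control libraries. These counts are unlike, since the first needs 0 in 2 libraries and the second 0 in 5. Over all genes detected in the other 5 libraries, 371 of 6513 were at 0 in both Cre libraries. Pairs of Control libraries gave 2 to 53 of 4866 to 5120 genes. These sets are unlike as well, since for Control pairs the other 5 libraries include both Cre libraries, which detected fewer genes.

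No gene higher in Cre passed edgeR (adjusted p = 0.214 to 0.277 for the 10 of lowest p). Both Cre libraries lay above every Control library for 7 of these. Rps24, a protein of the small ribosomal subunit, had 5933 ± 865 CPM in Control and 12773 ± 4159 CPM in Cre, a log2 difference of 1.12 ± 0.26. Arhgap9, a GTPase-activating protein, had 99.7 ± 47.7 CPM in Control and 421 ± 12.4 CPM in Cre. Psmc3ip, a recombination cofactor, had 0.472 ± 0.773 CPM in Control and 97.0 ± 2.33 CPM in Cre. Ndufb1-ps and the splicing factor Prpf38b had 118 ± 20.7 and 141 ± 21.8 CPM in Control against 401 ± 124 and 432 ± 156 CPM in Cre. Ncaph, a condensin subunit, and Mrpl15, of the mitochondrial ribosome, had Cre counts of 41 and 304 and of 132 and 771, with 0 to 2 and 2 to 47 counts in Control. The higher fitted value of 3 genes rested on 1 library. Twsg1 had 4494 counts in Cre replicate 1 and 8 in replicate 2, while Stag2 had 68 and 2891 and Slc35b1 57 and 1319.

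**Figure D2:**
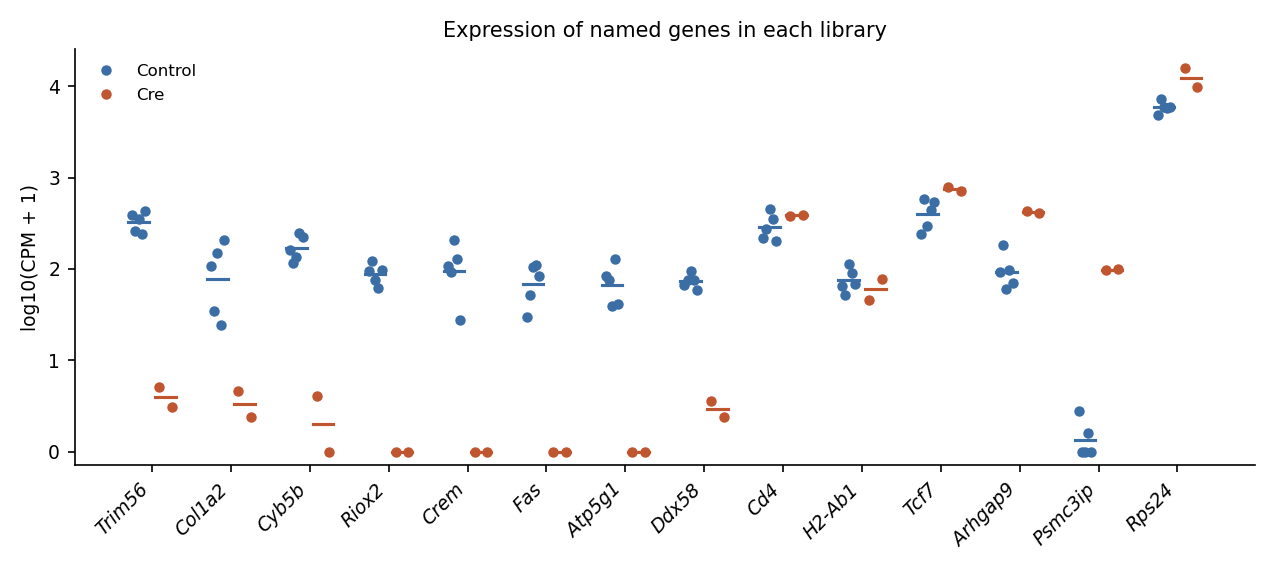
Expression of 14 named genes as log10(CPM + 1) in each library, with Control in blue (n = 5) and Cre in orange (n = 2). Points are libraries and bars the mean of the log values. Trim56 and Col1a2 lie near the detection limit in both Cre libraries, Riox2, Crem, Fas and Atp5g1 are at 0 there, and Cd4 and H2-Ab1 overlap between groups.

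Genes of the sorted cell type were present in both groups. Cd4 stood at 300 ± 104 CPM in Control and 385 ± 8.72 CPM in Cre. Cd3e had 146, 51, 307, 405 and 149 counts in Control and 116 and 3 in Cre. The 12 tested T cell receptor segment genes summed to 2902 to 4223 CPM in Control and to 3750 and 3718 CPM in Cre, and none passed the threshold (edgeR, 0 higher and 1 lower at an unadjusted p under 0.05; 0 in the authors' deposited table). H2-Ab1 (chromosome 17, 34257689 to 34269419) had 108, 76, 183, 153 and 110 counts in Control and 87 and 112 in Cre. Nearly all of them (99.8%) fell in 1 region at 34269109 to 34269668, where 311 of 560 bases are 3′ UTR. The deletion was aimed at fibroblasts, so H2-Ab1 in sorted T cells does not check it. H2-Aa was at 0 in both Cre libraries and at 0 to 42 counts in Control.

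Among T cell state lists, no member passed edgeR over all genes. Over all 9854 tested genes 60.1% had lower fitted values in Cre, which is a background for the counts of list members that is not matched on abundance. The median log2 fold change was −1.53 for genes under 30 CPM and 0.0006 for genes at 300 CPM or more. Counts of members in lists of low or high abundance may therefore differ from 60.1% through abundance alone. Both Cre libraries lay above every Control library for 4.05% of tested genes and below for 10.9%, where chance gives 4.76% each way. Members of smallest p were picked from each list, so such a position is no separate evidence. In the list of naive and central memory genes, 12 of 19 tested genes had higher fitted values in Cre, and the list did not pass camera (adjusted p = 0.49, unadjusted 0.0316, and 0.997 with an estimated correlation). Its member Tcf7, a transcription factor of naive and memory T cells, had 420 ± 150 CPM in Control and 749 ± 61.6 CPM in Cre, above every Control library. Satb1 had 292 ± 45.5 CPM in Control and 288 and 1028 CPM in the Cre libraries, with a log2 fold change of 0.02 without Cre replicate 2, and Foxo1 had 330 ± 99.7 and 151 ± 37.0 CPM. Of 25 T cell receptor signalling genes, 12 had higher and 13 lower fitted values in Cre, and the sign of their median turned with the scaling. Among them the adaptor Grap2 had 317 ± 90.6 CPM in Control and 580 ± 137 CPM in Cre, above every Control library. A region of Grap2 overlaps one of another gene on the same strand, so its counts may include those of that gene. Bcl10 and Malt1, partners in NF-kappaB activation, had 54.4 ± 42.9 and 186 ± 59.9 CPM in Control against 0.69 ± 0.976 and 60.9 ± 0.313 CPM in Cre. Of 23 activation genes, 12 had higher and 11 lower fitted values in Cre (median log2 fold change 0.12), with 0 higher and 1 lower at an unadjusted edgeR p under 0.05. The 4 of smallest p were all lower. Cd44 had 112 ± 31.5 CPM in Control and 26 and 0 counts in Cre, and Icos, Il2ra and Tnfrsf9 lay below every Control library in both Cre libraries. Of 18 genes of the Th1 and effector list, 10 had higher and 8 lower fitted values in Cre. Id2 had 713 ± 303 CPM in Control and 318 ± 112 CPM in Cre, Tbx21 179 ± 79.9 CPM in Control and 219 and 45.5 CPM in the Cre libraries, and Ifng 0 to 43 counts in Control and 217 and 0 in Cre. Of 21 regulatory T cell genes, 15 had lower fitted values in Cre, including Nrp1 and Il10, both at 0 in Cre. Foxp3 had 78.5 ± 43.9 CPM in Control and 56.5 and 4.14 CPM in the Cre libraries, with a log2 fold change of −0.44 without Cre replicate 2. Pdcd1 stood at 75.7 ± 55.5 CPM in Control and 85.1 ± 51.1 CPM in Cre. In the Th2 list, Stat6, the signal transducer of interleukin-4, had 117 ± 63.2 and 11.4 ± 7.33 CPM and was the only member that passed when adjusted over the list alone; the chemokine receptor Ccr4 was at 0 in both Cre libraries. Ccr2, in the list of chemokine receptors, had 112 ± 63.4 and 9.24 ± 11.1 CPM. Prf1, the cytotoxic pore protein, was at 0 in both Cre libraries and in 2 Control libraries. Of 7 tested Th17 genes, 6 had lower fitted values in Cre. All members of that list summed to 511 ± 157 CPM in Control and 44.0 and 379 CPM in the Cre libraries. Follicular helper genes summed to 784 ± 226 CPM in Control and 586 ± 303 CPM in Cre. Inhibitory receptor and exhaustion genes summed to 1430 ± 235 and 1501 ± 207 CPM, and tissue residency genes to 1743 ± 436 and 1547 ± 630 CPM.

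Lists of survival, division and metabolism had no member past edgeR over all genes and none passed camera. Fas in the pro-apoptotic list, Sesn1 in the senescence list and Atp5g1 in the oxidative phosphorylation list passed when adjusted over the list alone, and each had 0 counts in both Cre libraries. Sesn1, a stress-induced inhibitor of growth signalling, stood at 52.6 ± 24.3 CPM in Control, and Atp5g1, a subunit of the ATP synthase ring, at 72.6 ± 36.3 CPM. Of 56 oxidative phosphorylation genes, 6 were lower and 1 higher at an unadjusted p under 0.05. Ndufb8 of complex I had 87.8 ± 42.5 CPM in Control and 11.4 ± 4.38 CPM in Cre. Traf2, in the anti-apoptotic list, was at 0 in both Cre libraries. Bcl2 stood at 417 ± 195 and 227 ± 59.4 CPM. In the cell cycle list, 20 of 23 tested genes had lower fitted values in Cre, and its sum was 1012 ± 182 CPM in Control and 663 ± 240 CPM in Cre (exact permutation p = 0.19, adjusted 0.635 over the lists). The list was of low abundance (median logCPM 4.41), where lower values prevailed over all genes. Its members Mcm3 and Mcm7, of the replicative helicase, had means of 36.8 and 26.9 CPM in Control and 0.604 and 0.259 CPM in Cre, and Mki67 was at 0 in both Cre libraries and in 2 Control libraries. Glycolysis genes summed to 1872 ± 353 CPM in Control and 2186 ± 94.7 CPM in Cre, Akt-mTORC1 pathway and amino acid transporter genes to 4530 ± 708 and 4405 ± 643 CPM, and unfolded protein response genes to 3286 ± 906 and 3757 ± 326 CPM. Fatty acid oxidation genes summed to 596 ± 136 CPM in Control and 781 ± 40.9 CPM in Cre. Of the 16 tested, however, 11 had lower fitted values in Cre. Their median log2 fold change was −0.83, also with genes at 0 placed at their limit. Of these, Acadm had 17.3 ± 9.01 and 97.8 ± 63.6 CPM, and Echs1 was at 0 in both Cre libraries and in 1 Control library. Of 15 tested TGF-beta response genes, 11 had lower fitted values in Cre, and all members of that list summed to 860 ± 143 and 739 ± 388 CPM. Dissociation stress genes summed to 6948 ± 2134 and 6803 ± 3014 CPM. C1qbp, the receptor for the globular heads of C1q, had 209, 94, 122, 42 and 127 counts in Control and 162 and 0 in Cre.

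The 30 tested type I interferon response genes included 2 that passed when adjusted over the list alone. Ddx58, which encodes the RNA sensor RIG-I, had 73.4 ± 13.2 CPM in Control and 1.99 ± 0.856 CPM in Cre. Rsad2, the antiviral protein viperin, had 47.9 ± 38.2 CPM in Control and 0 counts in Cre. The list as a whole did not pass camera (adjusted p = 0.936), and its sum was 3709 ± 883 CPM in Control and 3917 ± 1131 CPM in Cre. Of 27 interferon-gamma-inducible genes, 4 were lower and 0 higher at an unadjusted p under 0.05, among them Gbp8 (0 counts in Cre, 38.3 ± 39.1 CPM in Control) and Gbp9 (0.345 and 43.6 CPM), while the list summed to 10607 ± 766 and 10694 ± 70.3 CPM.

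Ribosomal protein genes were the only list of 31 that passed camera, as higher in Cre (adjusted p = 0.0248), and the call was lost with an estimated correlation (adjusted p = 0.997). It was also lost without Control replicate 5 (adjusted p = 0.122), Cre replicate 1 (0.207) or Cre replicate 2 (0.213). None of its 63 members passed edgeR, where 2 were higher and 0 lower at an unadjusted p under 0.05, and 1, Rps24, passed DESeq2. Their median log2 fold change was 0.07 with TMM and 0.18 with DESeq2 size factors and turned to −0.04 with upper-quartile factors. That median lay at the 80.7th percentile of 10000 random lists matched on mean expression. The list held 104815 ± 12534 CPM in Control and 120352 ± 4905 CPM in Cre (exact permutation p = 0.19), and Rps25 had 1159 ± 504 and 2034 ± 292 CPM. No list passed as lower in Cre by camera, with 0 lower lists at an estimated correlation and 0 by fry; 2 lists had an unadjusted camera p under 0.05, both higher, and 10 had an unadjusted fry p under 0.05, all lower. No ribosomal gene was at 0 in both Cre libraries, and the median of all 9854 genes was −0.39 with TMM, also with the 1351 genes at 0 in both Cre libraries placed at their limit, and shifted by 0.10 with size factors and by −0.10 with upper-quartile factors, and 9 lists had a camera direction of higher, which compares them with other genes, beside a median below 0.

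Markers of other cell types were counted in both groups, and none of their lists with at least 5 tested genes passed camera. Their sums do not by themselves measure carry-over of those cells. Bst2 of the dendritic list is also in the type I interferon list, and Maf of the gamma-delta list is also in the Th2 list. The fibroblast list includes Thy1, which is not confined to fibroblasts. Fibroblast markers summed to 618 to 1050 CPM in Control and to 2232 and 364 CPM in Cre. Col1a2, the collagen gene whose promoter drives Cre, had 179, 50, 242, 40 and 336 counts in Control and 7 and 2 in Cre. It did not pass edgeR over all genes (adjusted p = 0.323), passed when adjusted over the list alone and passed DESeq2. Its counts came from 1 region on chromosome 6 at 4540663 to 4541793, of which 882 of 1131 bases are 3′ UTR. Bgn had 36.2 ± 38.3 and 1.64 ± 1.58 CPM, and Fn1 had 3374 counts in Cre replicate 1 and 39 in replicate 2, against 2 to 167 in Control. Macrophage and monocyte markers summed to 543, 680, 952, 511 and 7295 CPM in Control and 380 and 553 CPM in Cre. Lyz2 was at 0 in both Cre libraries and at 8 to 54 counts in Control, and Cd63 had 184 ± 91.5 and 47.4 ± 14.3 CPM. MHC class II presentation genes summed to 225 to 576 CPM in Control and to 659 and 520 CPM in Cre. Dendritic cell markers summed to 293 to 584 CPM in Control against 586 and 237 CPM in Cre, and neutrophil markers to 20.3 to 123 CPM against 43.5 and 113 CPM. B cell and plasma cell markers summed to 48.1 to 354 CPM in Control against 167 and 43.5 CPM in Cre, and NK and innate-like markers to 117 to 199 CPM against 196 and 146 CPM. Gamma-delta T cell markers summed to 226 to 502 CPM in Control against 524 and 454 CPM in Cre. CD8 T cell markers were at 0 in Cre and reached 9.49 CPM in Control. Epithelial and lung tumour markers summed to 0.614 to 25.2 CPM in Control against 58.0 and 1.38 CPM, endothelial markers to 64.5 to 144 CPM against 77.7 and 6.21 CPM, and erythroid markers to 1.16 to 100.8 CPM against 6.22 and 29.7 CPM.

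**Figure D3:**
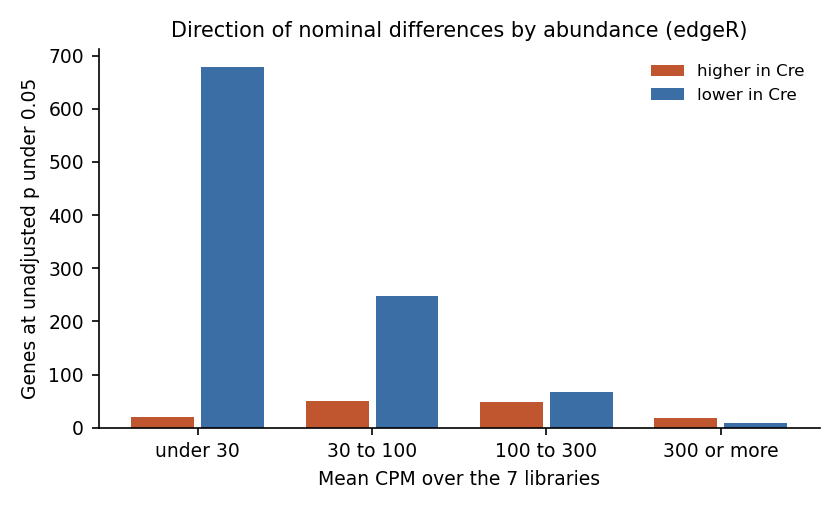
Number of genes at an unadjusted edgeR p under 0.05, higher (orange) or lower (blue) in Cre, in 4 classes of mean CPM over the 7 libraries. Under 30 CPM, 20 genes were higher and 678 lower, and at 300 CPM or more 19 were higher and 9 lower.

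The authors' deposited table gave 694 genes past an FDR of 0.05, 38 higher and 656 lower (94.5%) in Cre. Trim56 was at a log2 fold change of −6.38 in the authors' deposited table (FDR 5.47e-19). Of the 656 lower genes in the authors' deposited table, 370 (56.4%) had 0 counts in both Cre libraries. Among the 691 of these 694 genes that edgeR tested, all had the same sign in both fits, 647 had an unadjusted edgeR p under 0.05, 592 passed DESeq2 here and 1 passed edgeR. Across 9854 genes, which are not independent replicates, the log2 fold changes of the authors' deposited table and of edgeR had a Pearson r of 0.975 and a Spearman coefficient of 0.997. The direction of the calls varied with abundance. DESeq2 called 7 genes higher and 364 lower under 30 CPM, and 3 higher and 2 lower at 300 CPM or more.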

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

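The tests of depth, of the 21 splits of the libraries, of the other macrophage markers and of the other Trim56 region were chosen after the result was seen. Among 106 library measures, named genes and gene lists examined for a Control library far from the other Controls, 10 had one, where chance gives about 5.3. Control replicate 1 had 14849 genes with a count, against 10151 to 10843 in the other Controls. It also had the lowest sum of chemokine receptor and migration genes (2538 CPM, others 3574 to 3881). Ncaph was at a logCPM of 1.33 in Control replicate 1 and at 0.30 in the others, which held no count. Mrpl15 was at 1.27 in Control replicate 4, against 4.04 to 4.98. Abhd2 was at 7.16 in Control replicate 5, against 5.92 to 6.25, and in Control replicate 3 Foxo1 was at 7.27, against 8.37 to 8.66, and Grap2 at 7.30, against 8.37 to 8.63. T cell receptor signalling components summed to 9445 CPM in Control replicate 5 (others 6551 to 7348), and type I interferon response genes to 5223 CPM in Control replicate 2 (others 2905 to 3525). Macrophage and monocyte markers summed to 7295 CPM in Control replicate 5, against 511 to 952 CPM.

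Many more genes were lower than higher in Cre, by edgeR's unadjusted p and by DESeq2. Lower depth of the Cre libraries is argued against by 8759 genes in the better Cre library at an equal total, under the lowest Control library (9983). Unequal recovery by GC content stays open. The lowest share of lower DESeq2 calls in 4 equal classes of genes by GC was 90.1%, which by the rule set beforehand would argue against it. That rule was set aside, because on unchanged genes simulated from edgeR's fit DESeq2 also gave mostly lower calls (91.8 lower and 8.2 higher on average). Those calls are fewer than the 607 lower and 35 higher in the data, so the simulation does not by itself account for the share in each class. Independent loss of transcripts in each Cre library stays open. Genes at 0 in both were 1.38 times the number expected from each library's own zeros (371 against 269.7). That ratio was under that of the other 20 pairs (1.56 to 3.68), as predicted for independent loss, but the ranking cannot decide. Where zeros are common the ratio has a lower ceiling. The Cre libraries had 857 and 1323 zeros among 6513 genes, so their ratio could not have exceeded the highest other pair. A Mantel-Haenszel odds ratio of joint zeros over classes of expression, which lacks this ceiling, was also lowest for the Cre pair (2.01, others 2.25 to 7.66). The pairs rest on unlike sets of genes, so that ranking does not decide either. Of the 21 splits 1, the real one, gave as many as 642 DESeq2 calls and the highest other gave 196, which is the smallest share 21 splits allow and holds for any property these 2 libraries share, such as their many genes at 0; an effect of the genotype stays open too and was not tested apart from such properties.

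Trim56 was lower in Cre, in a class of abundance (100 to 300 CPM) where 57.8% of genes at an unadjusted edgeR p under 0.05 were lower. A count of 1 edgeR call does not by itself exclude chance, since 2 of the 21 splits gave at least 1 call and the highest other gave 1. Loss or silencing of the chromosome segment stays open. The 27 other tested genes within 1 Mb, 17 of them lower, had a median log2 fold change of −0.81. That lay within the range of random sets of tested genes (−1.47 to 0.27), which by the rule set beforehand would argue against it. Sets this small vary too widely to decide, and a median over the window cannot show a loss of few genes. The nearest tested gene on each side, Ap1s1 (−0.82) and Srrt (−1.51), was lower but did not pass edgeR (adjusted p = 0.89 and 0.702). A sequence difference in the counted 3 prime region of Trim56, such as a strain variant, stays open, because the other counted region of the gene held 0 counts in all 7 libraries. An effect of the genotype on Trim56 in T cells may be a candidate explanation as well and was not tested.

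Single libraries held most of the counts of some genes: 48 genes had at least 100 CPM in one library and at least 20 times the next highest library. The largest, chosen after their values were seen, were Pygb (30325 CPM in Control replicate 3, next 171), Ndufa3 (16449 CPM in Control replicate 4, next 248) and Apoe (6676 CPM in Control replicate 5, next 23.4). Macrophage RNA in Control replicate 5 is argued against as the source of Apoe, since the other macrophage and monocyte markers summed to 619 CPM there, within the range of the other Controls (511 to 929). For a property of the Cre group, Cre replicate 1 tied with the highest Control libraries (7 genes each) while Cre replicate 2 held 17. The rule set beforehand counts such a tie against that explanation. This reading was changed after the result was seen, to one where a tie cannot tell it apart from chance differences between libraries. Uneven amplification of few molecules was not tested, and no biological explanation was tested.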

How the results depend on the processing

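The alternatives named as chosen after seeing the data were added only then. Trim56 kept its direction under every alternative run and its call under all but limma voom (adjusted p = 0.222) and voom with library weights (adjusted p = 0.789); its adjusted p ran from 0.0063 to 0.0484 over the leave-one-out edgeR fits. The edgeR counts stayed at 0 higher and 1 lower with DESeq2 size factors, upper-quartile factors and the stricter filter, and with 3 alternatives chosen after seeing the data (genes of at least 100 CPM, no genes overlapping another, no robust estimation). Without a filter, edgeR called 15 higher and 28 lower; the cause was not tested. DESeq2 called 35 higher and 607 lower, limma voom 3 and 0, and voom with library weights 1 and 0; the cause was not tested. On genes of at least 100 CPM, an alternative chosen after seeing the data, DESeq2 called 4 higher and 9 lower. Leaving out 1 library, edgeR called 0 to 17 genes higher and 1 to 202 lower, the highest without Cre replicate 1, and DESeq2, added after seeing the data, 31 to 93 higher and 380 to 1510 lower (fewest lower without Control replicate 1, most without Cre replicate 1). With 1 Cre library left, that library is assumed to vary like the Controls. The number of lists higher in Cre was 0 to 1 over the libraries left out, lost without Control replicate 5 or either Cre replicate, and 0 with upper-quartile factors, the stricter filter, an estimated correlation or fry; the adjusted p of the ribosomal list ran from 0.000531 (no filter) to 0.997 (estimated correlation). Replicate numbers are shared by 2 libraries per group and nothing in the labels says that they mark a litter or day. With the number as a block edgeR called 5 genes lower, and 1 list as higher; the deviations of same-numbered libraries correlated at 0.003 and 0.002 across genes. H2-Ab1 had a log2 fold change of 0.0011 under the block. Signs of 9 named genes turned when 1 library was left out. Over the libraries left out, the log2 fold change ran from −0.63 to 0.72 for Pdcd1 (−0.11 without Control replicate 2), −1.82 to 6.92 for Twsg1, −0.72 to 0.023 for H2-Ab1 (highest without Cre replicate 1), −7.24 to 3.30 for Ifng, −0.62 to 5.44 for Fn1, −0.37 to 5.41 for Stag2, −0.27 to 4.64 for Slc35b1, −9.88 to 0.24 for C1qbp and −1.96 to 0.34 for Tbx21. Of the other values of named genes, 1089 kept direction and side of the threshold, 78 became calls and 2, both of Trim56, lost one. Depth limits single values to about 1.55 to 2.07 CPM per library.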

Other observations

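The counts of sex-linked transcripts were singled out only after their values were seen. The hypothesis that a fixed list makes up more of the authors' lower genes than chance was tested by Fisher's exact test over 31 lists, with the 9854 tested genes as background, of which 656 were lower in the authors' deposited table. The number of lists past an adjusted p of 0.05 with more members than expected was 0, so no fixed list enriched among the genes lower in the authors' table was found. Fibroblast markers had 2 of 9 members there, where 0.599 were expected (unadjusted p = 0.117), and ribosomal protein genes 0 of 63, where 4.19 were expected (unadjusted p = 0.0211, adjusted 0.654).

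Counts of sex-linked transcripts went against an even match of the sexes over the libraries, although the series design calls the mice gender-matched, and the sex of each mouse is not given in the sources used here. Ddx3y was counted in both Cre libraries and was at 0 to 2 counts in Control replicates 1, 4 and 5, while Control replicates 2 and 3 held 34 and 141. Trim56 had 382 and 565 counts in Control replicates 2 and 3 and 8 and 3 in Cre, so its level did not follow that of Ddx3y. Libraries that pool mice are not excluded. Xist had 340, 16, 76, 266 and 476 counts in Control replicates 1 to 5 and 1 and 86 in the Cre libraries. Ddx3y had 1, 34, 141, 2 and 0 counts in Control and 76 and 89 in Cre, and Uty had 0, 48, 121, 2 and 0 in Control and 2 and 126 in Cre. Eif2s3y had counts in Control replicates 2 and 3 (17 and 18) and in Cre replicate 1 (28), and Kdm5d had 68 in Control replicate 2.

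Pseudogenes took 9.004 ± 1.995% of counts in Control and 8.84 ± 0.428% in Cre (exact permutation p = 1), and snoRNAs 3.77 ± 0.472% and 4.51 ± 0.175% (exact permutation p = 0.19).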
